A study of Mus musculus with 8 samples.

How the data were processed

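Binding of Chaf1a, Zfp809, Sumo2 and Trim28 was measured by ChIP-seq, with 1 ChIP library and 1 control library for each factor. The values analysed here are 4 deposited peak lists, 1 per ChIP library, each called against its own control. The control libraries entered only through the control tags given for each peak and had no list of their own. STAR, HOMER and the mouse build mm9 are named in the submitters' processing notes, without versions. Column names show lists written by HOMER's findPeaks, per the file headers, with 15 columns per list. Alignment settings, the handling of reads that map to several places and the peak calling options are not given in the sources used here. This matters for endogenous retroviruses, whose copies share sequence, because the treatment of multiply mapping reads decides which copies can carry a peak.

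The normalised tag count of each peak, the ChIP tags and the control tags are signal values that the authors deposited after scaling by library depth. ChIP tags were scaled to the control library for Chaf1a and Zfp809, and control tags to the ChIP library for Sumo2 and Trim28, per the file headers. The findPeaks score is a score without a fixed scale, deposited by the authors, and was used only to rank and describe peaks within a list. Fold change over control and over the local surroundings is a ratio computed by the authors' peak caller, as is the clonal fold change. The minimum fold over control was 4.00 in 3 of the lists and 4.01 in that of Sumo2, which shows that the lists had been filtered before deposit. The focus ratio is a deposited fraction of tags on the side of the peak centre where they belong, and it was used only to describe single peaks. The p-value of each peak, deposited by the authors, was at most 9.94e-05 against the control and the local surroundings, and was not used in a test.

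Library depth was worked out from the steps of the normalised tag count, taking the default of HOMER, which scales to 10 M tags. The step was read as 0.5 tags in 3 lists and as 1 tag in that of Sumo2. For Sumo2 and Trim28 the ratio of total to normalised tags gave nearly the same depth, 17.3 and 15.0 M tags. Both values assume the same scaling, so that ratio can check only how the step was read, not the scaling. For the other lists that ratio gives the control depth, 29.4 M for Chaf1a and 11.5 M for Zfp809. The depth of the input libraries is unknown here.

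Overlaps were counted in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Peaks were shared when they overlapped by at least 1 bp, since a wide and a narrow peak of the same site must count as shared. For each pair, the peaks of the shorter list that met the longer list were counted, and the longer list was then shifted in a circle along each chromosome 1000 times with seed 20. Chromosome length was taken as the largest peak end over the 4 lists. Regions were merged over the 4 lists, and bedtools 2.31.1 gave the same 79564 regions and 927 with all factors. Shares carry Wilson intervals and counts exact Poisson intervals at the 95% level, and medians carry intervals from order statistics. These intervals treat peaks as independent and cover counting error only, not the variation between cultures. The counting was tested on simulated lists of the real sizes: of 3000 planted overlaps, 99.6% were recovered for Chaf1a and Trim28, 99.1% for Zfp809 and Trim28, 99.1% for Trim28 and Sumo2 and 99.7% for Chaf1a and Zfp809, and 600 of 600 planted sites with all 4 lists. Planted peaks overlapped by construction and the others were placed at random. The simulation therefore checked the counting code only, not the shifts on clustered peaks.

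The sites named were fixed by a rule set before the data were examined: the 10 peaks with the highest score per list and the 10 sites with all 4 factors that have the highest mean score percentile, on placed chromosomes only. The rule asked for their nearest genes, with positions to be given where the files name none, and positions are what the text gives. The gene table at hand was of build GRCm38, and coordinates were not moved between builds. For the same reason the share of peaks in retroviral long terminal repeats, their place relative to genes, counts over preset gene lists and peaks near the genes of the 4 factors were not analysed here.

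Alternatives set before the data were examined were a fold over control of at least 8, an overlap of at least 50% of the smaller peak, centres within 1000 bp, lists cut to their 11354 strongest peaks, and fold over control in place of the score. Alternatives added after seeing the data were shifts of 20 to 200 kb, shifts of the Chaf1a list alone, lists without the 5% of peaks with the most control tags, and autosomes only. The split by chromosome, the split by a further factor, the tiers of strongest peaks, windows of 1 Mb and distances between peaks were likewise chosen after the lists had been examined.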

Results

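Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 4 proteins in undifferentiated mouse cells. By its title and design text, the series addresses how proviruses and endogenous retroviruses are silenced in embryonic stem cells. Chaf1a, the large subunit of the chromatin assembly factor that deposits histones behind the replication fork, was mapped in F9 embryonal carcinoma cells through HA epitopes added to the endogenous gene by CRISPR. Zfp809, a KRAB zinc finger protein known to recognise the proline primer binding site of murine leukaemia viruses, was mapped in ES-D3 embryonic stem cells through the HA tag of a transiently expressed isoform. Sumo2, a small ubiquitin-like modifier, and Trim28, the corepressor recruited by KRAB zinc finger proteins and also called KAP-1, were mapped in E14 embryonic stem cells with antibodies against the native proteins. The antibody used for Sumo2 also recognises Sumo3, per the labels. Each of the 4 ChIP libraries had a control library of its own, an HA ChIP of control cells for Chaf1a and Zfp809 and input DNA for Sumo2 and Trim28, which makes 8 libraries. There was 1 ChIP library per factor, so no comparison had a replicate, no p-value between factors was computed, and all intervals cover counting error only. Factor and cell line changed together except for Sumo2 and Trim28, and the antibody, kind of control and depth differed as well.

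The longest list was that of Sumo2, with 51628 peaks, followed by Trim28 with 24255, Zfp809 with 18197 and Chaf1a with 11354. Chaf1a peaks were 140 bp wide, Sumo2 peaks 136 bp, Zfp809 peaks 176 bp and Trim28 peaks 470 bp, a width that all but a few peaks of a list shared. The median enrichment over the matched control was 18.5-fold for Sumo2, 14.1-fold for Zfp809, 7.57-fold for Trim28 and 7.56-fold for Chaf1a. Control tags stood at the lowest value of the list, 0.5 tags, for 51.9% of Zfp809 peaks, 34.9% of Sumo2 peaks and 13.7% of Chaf1a peaks, and at 0.3 tags for 0.689% of Trim28 peaks, so folds are not exact there. The median folds, and the shares at 8-fold that follow, describe each list and do not rank the factors. Enrichment of at least 8-fold was met by 43826 Sumo2 peaks (84.9%) and 15378 Zfp809 peaks (84.5%), and by 11169 Trim28 peaks (46.0%) and 5330 Chaf1a peaks (46.9%). The scaled tag values put the ChIP libraries at 31.1 M tags for Chaf1a, 19.2 M for Zfp809, 17.3 M for Sumo2 and 15.1 M for Trim28, if the peak caller's default scaling was used. The number of peaks therefore did not follow depth, since the deepest library gave the shortest list. A typical peak rested on few tags. The median was 15.99 ChIP tags for Chaf1a, where a Poisson interval at the 95% level runs from 9.14 to 26.0, then 17.5 for Zfp809, 15.0 for Sumo2 and 22.5 for Trim28.

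Peaks of all 4 factors were found on the autosomes and on chromosomes X and Y, with differences in density. The gene-rich chromosome 11 held the densest Chaf1a peaks, 6.39 per Mb against 4.19 over all sequence, while Zfp809, Sumo2 and Trim28 were densest on chromosome 17, with 8.71, 23.4 and 11.2 peaks per Mb. Chromosome X carried fewer peaks per Mb than all sequence together for each factor, from 2.21 for Chaf1a to 13.2 for Sumo2. Taken as a ratio between lists, the shares differed most on chromosome Y, counted together with its unplaced sequence. It held 11 of the 11354 Chaf1a peaks, or 0.0969% (95% Wilson interval 0.0541 to 0.173), against 1.26% of Zfp809 peaks (1.11 to 1.43), 1.17% of Sumo2 peaks (1.08 to 1.27) and 0.800% of Trim28 peaks (0.695 to 0.920). Among the 11354 strongest peaks of each list, the Y counts were 116 for Zfp809, 126 for Sumo2 and 72 for Trim28. The handling of reads that map to several places is not given, and the Y counts may depend on it. The split by chromosome was chosen after the lists had been examined, and it cannot separate the factor from the cell line, since Chaf1a alone was mapped in F9 cells.

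**Figure D1:**
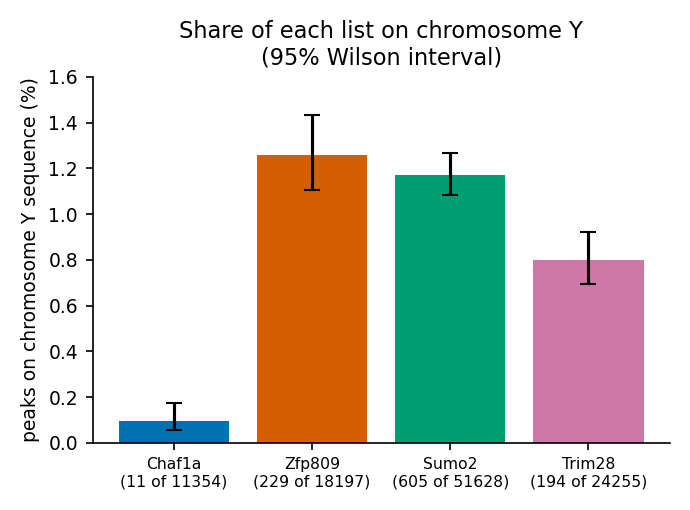
Share of each peak list that lay on chromosome Y sequence, unplaced Y sequence included, in percent of all peaks of the list, with bars for the 4 factors and error bars for 95% Wilson intervals. The Chaf1a bar stands at 0.0969% and the other 3 between 0.800% and 1.26%.

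The first question was whether the factors were found at the same places. Sumo2 and Trim28, mapped in the same cell line, met most often. Of the 24255 Trim28 peaks, 13823 or 57.0% (56.4 to 57.6) overlapped a Sumo2 peak by at least 1 bp. Chaf1a, although mapped in another cell type, met Trim28 at 3710 peaks or 32.7% of its list (31.8 to 33.5) and Sumo2 at 3272 or 28.8% (28.0 to 29.7), but Zfp809 at only 1132 or 9.97% (9.43 to 10.5). Zfp809 met Sumo2 at 5540 of its peaks or 30.4% (29.8 to 31.1) and Trim28 at 4144 or 22.8% (22.2 to 23.4).

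Each of these counts was set against 1000 circular shifts of one list along its chromosomes. Shifted lists met at a mean of 24.7 peaks for Chaf1a and Zfp809, 61.5 for Chaf1a and Sumo2, 64.5 for Chaf1a and Trim28, 109.8 for Zfp809 and Sumo2, 108 for Zfp809 and Trim28, and 283 for Trim28 and Sumo2. Observed overlap was thus 45.8, 53.2, 57.5, 50.5, 38.5 and 48.8 times the shifted mean, in the same order. The highest shifted count was 41 for Chaf1a and Zfp809 and 335 for Trim28 and Sumo2, far below what was observed. The size of the excess depended on the settings, from 10.3-fold for Chaf1a and Sumo2 when centres within 1000 bp counted as shared to 164-fold for Sumo2 and Trim28 when lists were matched in length, and every pair stayed above its highest shifted count under each setting. Shifts of 20 to 200 kb, which keep regional peak density, left excesses of 28.1-fold to 37.1-fold. Shares moved as well: among peaks at least 8-fold over control, 19.12% of Chaf1a peaks and 15.1% of Zfp809 peaks met Trim28, lists of equal size left 13.9% of Chaf1a peaks with Sumo2, and with centres within 1000 bp 16.6% of Chaf1a peaks met Zfp809.

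**Figure D2:**
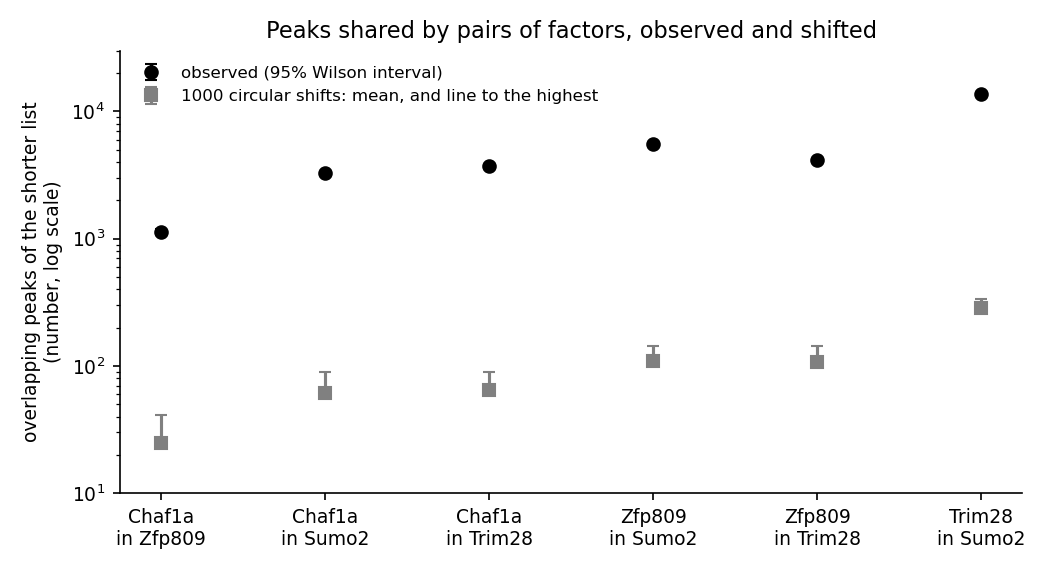
Number of peaks of the shorter list that overlapped the longer list for the 6 pairs of factors, on a logarithmic axis. Black points are the observed counts with 95% Wilson intervals (smaller than the points), and grey squares with lines are the mean and the highest of 1000 circular shifts. Observed counts lie between 1132 and 13823 and shifted means between 24.7 and 283.

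The presence of one further factor went with large differences in these shares. This split, like the shares by rank of score given further on, was chosen after the lists had been examined. Zfp809 peaks that also carried Trim28 overlapped Sumo2 in 76.3% of cases (74.9 to 77.5), against 16.9% (16.3 to 17.6) of Zfp809 peaks without Trim28. The same peaks overlapped Chaf1a in 20.9% of cases (19.7 to 22.1) with Trim28 and 1.90% (1.69 to 2.14) without it. Chaf1a peaks that carried Zfp809 met Trim28 in 76.6% of cases (74.0 to 79.0), against 27.8% (27.0 to 28.7) of those without Zfp809. Trim28 peaks gave a contrast between both HA-tagged factors. Those with Sumo2 overlapped Zfp809 in 25.1% of cases (24.4 to 25.9) and those without Sumo2 in 6.27% (5.82 to 6.75), whereas Chaf1a was met by 14.9% (14.3 to 15.5) of the former and 15.7% (15.0 to 16.4) of the latter, values whose intervals overlap. None of these splits matched peaks for score. Across 10 score groups of Trim28 peaks, the share with Sumo2 fell from 92.0% to 41.7% and that with Chaf1a from 36.1% to 5.28%. Score alone would thus make Chaf1a more frequent at Trim28 peaks with Sumo2 than at those without, and it was not. Similar shares with Chaf1a therefore do not show that it is unrelated to Sumo2, and the relation at equal score was not tested. In the Chaf1a list, peaks with Sumo2 met Trim28 in 55.2% of cases and those without Sumo2 in 23.6%. That split relates Sumo2 to Trim28 and does not settle how Chaf1a relates to Sumo2.

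Whether the 4 factors act at the same endogenous retroviruses was approached here only at the level of peaks, by the number of sites carrying all of them. The merged lists formed 79564 regions. Most held a single factor, 59726 regions or 75.1%, of which 33901 had Sumo2 alone, 11529 Zfp809 alone, 8264 Trim28 alone and 6032 Chaf1a alone. Of the 14946 regions with 2 factors, 9195 combined Sumo2 and Trim28, and only 142 combined Chaf1a and Zfp809. Among 3965 regions with 3 factors, the combination of Zfp809, Sumo2 and Trim28 led with 2579, followed by Chaf1a, Sumo2 and Trim28 with 1145.

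All 4 factors were present at 927 regions, or 1.17% of the total (Poisson interval of the count 868 to 989). Merging chains peaks, so the peaks of such a region need not all overlap each other. Direct overlap with all 3 other factors was found for 725 Chaf1a, 742 Zfp809, 737 Sumo2 and 917 Trim28 peaks. When 3 lists were shifted independently, the mean was 0.002 such regions and the highest of 1000 shifts gave 1. When the Chaf1a list alone was shifted and the other 3 stayed in place, the mean was 9.26 and the highest 20, so that the observed number was 100.2 times that mean. Chaf1a was present at 26.4% (25.01 to 27.9) of the 3506 regions that carried Zfp809, Sumo2 and Trim28. The count depended on the threshold and was 372 among peaks at least 8-fold over control.

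**Figure D3:**
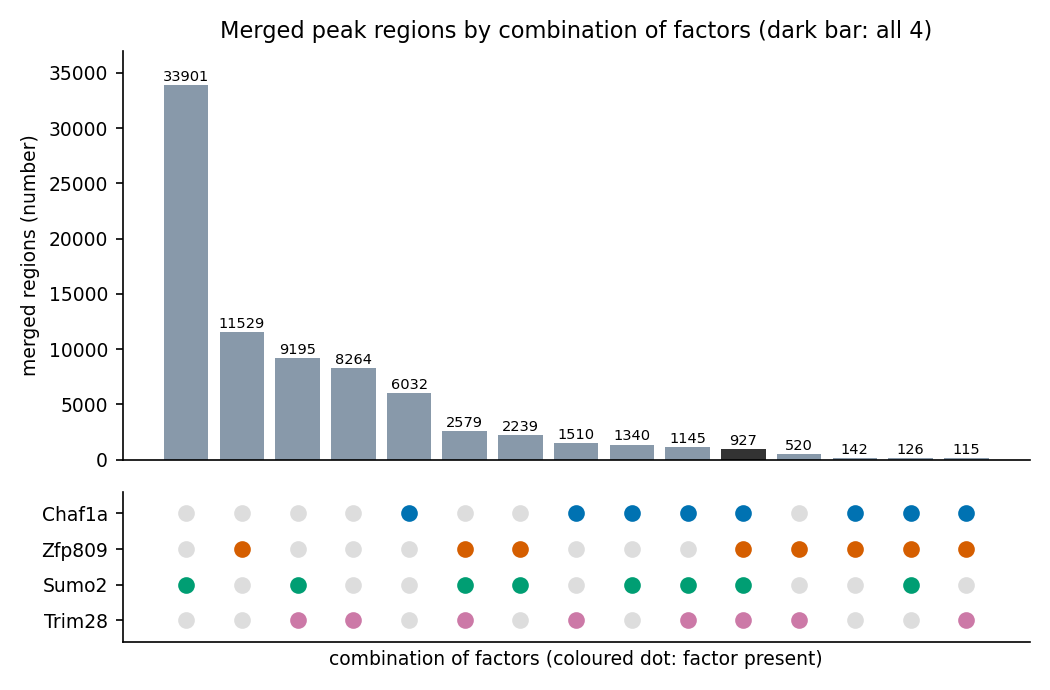
Number of merged regions for each of the 15 combinations of factors, in falling order, with coloured dots under each bar for the factors present. Sumo2 alone leads with 33901 regions, and the dark bar marks the 927 regions with all 4 factors.

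The sites with the highest mean score percentile over the 4 lists lay at 10 places of the mm9 build. First was chromosome 4 from 152527012 to 152527482, where the authors' scores were 1311 for Trim28, 999 for Sumo2, 747 for Chaf1a and 738 for Zfp809. The second, chromosome 3 from 148715332 to 148715802, scored 1138 for Trim28, 824 for Chaf1a, 717 for Sumo2 and 605 for Zfp809. The next was chromosome 6 from 4873728 to 4874198, with 721 for Trim28, 628 for Sumo2, 473.5 for Chaf1a and 437 for Zfp809. After these came chromosome 7 from 7230603 to 7231188, chromosome 7 from 89919743 to 89920566, chromosome 17 from 63086692 to 63087162, chromosome X from 125590898 to 125591368, chromosome 9 from 96753274 to 96753744, chromosome X from 137710929 to 137711399 and chromosome 8 from 20020191 to 20020661. The first 3 of these sites were also among the 10 strongest peaks of every list. Control libraries were high at these places too: 38 of the 40 peaks lay above the 95th percentile of control tags of their own list, and their median percentile was 99.9. At the site on chromosome 4, the controls held 74.5 tags for Chaf1a, 51 for Zfp809, 82.7 for Sumo2 and 121 for Trim28, where the list medians were 2, 0.5, 1 and 3. Enrichment over those controls was 10.8-fold for Chaf1a, 10.5-fold for Zfp809, 46.6-fold for Sumo2 and 15.0-fold for Trim28. Which genes or repeats lie at these positions was not analysed here, since the annotation at hand was of another build.

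Among the 10 strongest peaks of each list, 8 of Chaf1a, 5 of Trim28, 3 of Zfp809 and 3 of Sumo2 directly overlapped all other factors. Control tags were high at most of these 10 peaks per list. Their lowest percentile within the list was 99.8 for Chaf1a, 99.6 for Sumo2 and 99.9 for Trim28. The lowest folds over control were 5.87, 7.02 and 4.39. For Zfp809 the median percentile was 99.8, with single peaks far lower. Whether high control coverage lifted these overlaps was not tested. The Chaf1a peak on chromosome 7 from 7231048 to 7231188, in a merged site named above, overlapped only 1 other factor directly. The strongest Chaf1a peak was that on chromosome 3, and the strongest Zfp809 peak lay on chromosome 7 from 89919743 to 89919919, with a score of 864 and 23.4-fold enrichment. Zfp809 peaks could be strong over a low control: the one on chromosome 19 from 37701858 to 37702034 stood 649-fold over a control of 1 tag and met 2 other factors.

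Peaks met by 3 other factors were stronger than peaks met by none, by different amounts, though the rise between was not steady for Zfp809. Median score in the Sumo2 list was 13 (95% interval 13 to 13) for peaks met by no other factor, 19 for those met by 1, 32 for those met by 2 and 61 (58 to 65) for those met by 3, a ratio of 4.69 (4.46 to 5.00) between the ends. In the Trim28 list it went from 20 (20 to 20.5) through 23.5 and 30 to 51 (49 to 52.5), a ratio of 2.55 (2.39 to 2.63). The Chaf1a list showed a small rise, from 15.5 (15.5 to 15.5) to 18.5 (18 to 19), a ratio of 1.19 (1.16 to 1.23). Zfp809 peaks went from 30 (30 to 30) through 29 and 32 to 38 (37 to 40), a ratio of 1.27 (1.23 to 1.33). Scores were compared only within a list.

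Read from the other side, overlap was lower among the lower-scoring 50% of peaks than among the 1000 strongest in all 4 lists. Of the 1000 strongest Trim28 peaks, 94.5% (92.9 to 95.8) met Sumo2, 58.0% (54.9 to 61.0) Zfp809 and 47.2% (44.1 to 50.3) Chaf1a, while among the 12128 weakest the shares were 44.9%, 9.25% and 9.29%. The 1000 strongest Sumo2 peaks met Trim28 in 81.0% of cases (78.5 to 83.3), Zfp809 in 58.7% (55.6 to 61.7) and Chaf1a in 42.3% (39.3 to 45.4), and the 25814 weakest in 13.6%, 4.14% and 3.91%. The 1000 strongest Chaf1a peaks met Trim28 in 52.5% of cases (49.4 to 55.6), Sumo2 in 50.2% (47.1 to 53.3) and Zfp809 in 23.6% (21.1 to 26.3), and the 5677 weakest in 25.5%, 22.95% and 6.78%. The 1000 strongest Zfp809 peaks met Sumo2 in 37.6% of cases (34.7 to 40.6), Trim28 in 29.7% (27.0 to 32.6) and Chaf1a in 7.70% (6.21 to 9.52). For the 9099 weakest the shares were 29.0%, 19.7% and 4.79%. In this list the share with Sumo2 showed no steady fall across 10 score groups of equal size. It went from 32.0% (29.9 to 34.2) in the group with the highest scores to 33.5% (31.4 to 35.7) in that with the lowest, with a low of 25.1% (23.2 to 27.2) in group 8, whereas the share with Trim28 went from 27.1% (25.1 to 29.2) to 19.02% (17.3 to 20.9) and that with Chaf1a from 8.63% (7.42 to 10.0) to 4.34% (3.5 to 5.38). The 100 strongest Zfp809 peaks met Sumo2 in 87% of cases (79.0 to 92.2) and Trim28 in 67% (57.3 to 75.4), above the shares of the 1000 strongest. Without the 5% of peaks with the most control tags in each list, the 1000 strongest Zfp809 peaks met Sumo2 in 30.6% of cases (27.8 to 33.5) and Trim28 in 25.3% (22.7 to 28.1). The 100 strongest then met Sumo2 in 82% (73.3 to 88.3) and Trim28 in 59% (49.2 to 68.1). Shares of the weakest peaks were not computed for lists cut in this way, so the 9099 weakest are not a like comparison. The share of the 100 strongest with Chaf1a, 12% (7.0 to 19.8), had an interval that overlapped that of the 1000 strongest, 7.70% (6.21 to 9.52), and was 7% (3.43 to 13.8) when the 5% of peaks with the most control tags were left out.

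**Figure D4:**
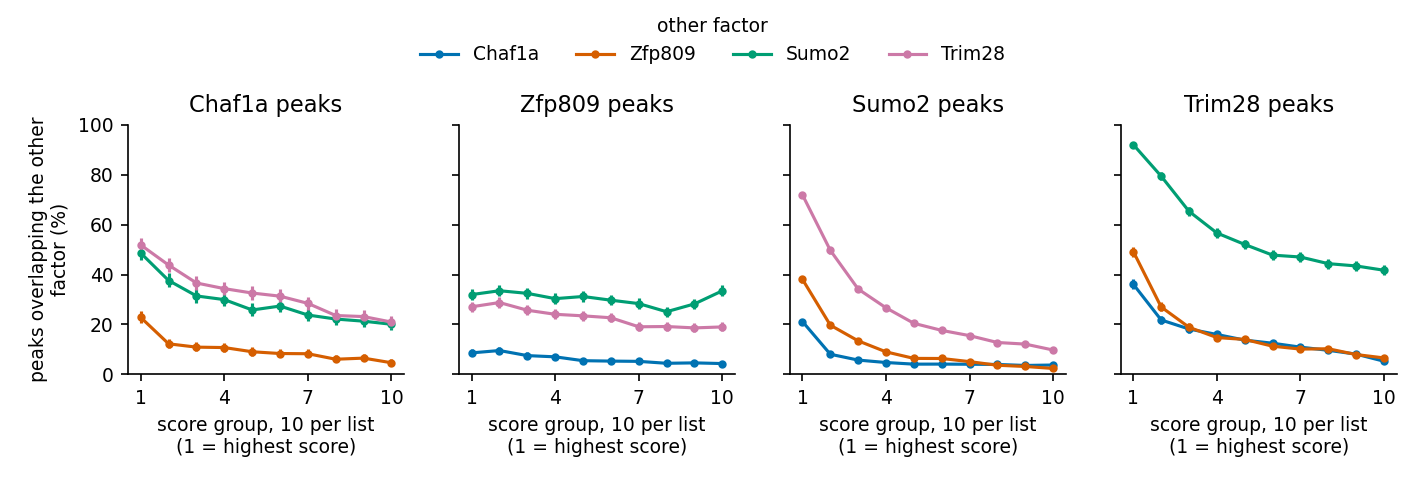
Share of peaks that overlapped each of the other factors, in percent, across 10 groups of equal size in each list by the authors' score (1 is the group with the highest scores), with lines for the other factors and error bars for 95% Wilson intervals. Lines fall for Chaf1a, Sumo2 and Trim28 peaks, whereas the share of Zfp809 peaks with Sumo2 starts at 32.0%, dips to 25.1% and ends at 33.5%.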

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

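Shifts of 20 to 200 kb, shifts of the Chaf1a list alone, lists without the 5% of peaks with the most control tags and autosomes only were alternatives chosen after the result was seen. No value changed direction under any alternative run, and each pairwise overlap stayed above its highest shifted count. In what follows, pairs come in the order Chaf1a with Zfp809, with Sumo2 and with Trim28, Zfp809 with Sumo2 and with Trim28, and Sumo2 with Trim28, and values are observed over mean shifted overlap. An overlap of at least 50% of the smaller peak gave 60.0, 83.8, 71.8, 76.0, 48.7 and 60.9. Centres within 1000 bp, a criterion that shifted lists meet more often, gave 12.5, 10.3, 20.3, 12.3, 17.0 and 16.5. The same number of strongest peaks per list gave 52.2, 117, 81.4, 154, 67.7 and 164. A fold over control of at least 8 gave 49.3, 58.9, 74.1, 51.6, 56.0 and 68.2. Shifts of 20 to 200 kb gave 30.2, 37.0, 36.7, 37.1, 28.1 and 36.5. Without the 5% of peaks with the most control tags the first 5 pairs stood at 42.5, 50.98, 55.3, 46.4 and 37.0, and Sumo2 with Trim28 moved by less than its interval. On autosomes the last 3 pairs stood at 48.3, 37.1 and 47.6, and the 3 pairs with Chaf1a moved by less than their intervals. The order of the pairs changed with the setting, so it should not be read as a ranking of the factors.

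A fold over control of at least 8 left 5330 Chaf1a and 11169 Trim28 peaks and 372 sites with all 4 factors, by construction fewer than before. Other settings kept that last count within 1.5-fold of 927, namely 1155 with centres within 1000 bp of the Chaf1a centre, 624 with lists of equal size, 692 without the 5% of peaks with the most control tags and 874 on autosomes. The ratio of median strength between peaks met by 3 other factors and by none moved for Chaf1a to 1.16 with fold over control and 1.13 without the 5% of peaks with the most control tags, and for Zfp809 to 1.16 and 1.2. The cause was not tested, and the ratios for Sumo2 and Trim28 stayed within their intervals. Alternatives planned for repeat elements, genomic location and gene lists were not run, as those results were not computed. With 1 library per factor, a peak missing from a list at a median of 15.0 to 22.5 tags is not evidence of absence.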

Other observations

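All windows, spacing tests and comparisons of control tags at the strongest sites in this part were chosen after the lists had been examined, except that the shift of 20 to 200 kb, the removal of high control peaks and the comparison of peak pairs with similar tag counts had their outcome criteria written down before the values were computed. Peaks gathered in particular megabases, some of them shared between factors. The densest 1 Mb window for Chaf1a was chromosome 13 from 21 to 22 Mb, with 42 peaks where the median window had 3, and next came chromosome 3 from 96 to 97 Mb with 31. The main histone gene cluster of the mouse lies on chromosome 13 and a smaller one on chromosome 3, and whether these windows cover them was not tested without an annotation of the build. Sumo2 was densest nearby, on chromosome 13 from 23 to 24 Mb, with 85 peaks against a median of 18. Zfp809 had 50 peaks on chromosome 12 from 18 to 19 Mb, 41 on chromosome 13 from 66 to 67 Mb and 41 on chromosome 4 from 145 to 146 Mb, against a median of 6, and the window on chromosome 13 was also the second densest for Sumo2, with 75. In the Trim28 list, chromosome 7 from 30 to 31 Mb led with 40 peaks against a median of 8. Across the 2588 windows, which are not independent replicates, Spearman's rho of peak numbers ran from 0.601 for Chaf1a and Zfp809 to 0.816 for Sumo2 and Trim28, with Pearson's r of 0.599 and 0.804.

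Peaks were also frequent in the first sequenced megabase of the chromosomes, which in this build begins next to the centromere. The density there was 2.11 times that of the rest for Zfp809, 1.90 times for Sumo2, 1.61 times for Trim28 and 1.31 times for Chaf1a.

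One of the 10 strongest Zfp809 peaks stood in no other list. It lay on chromosome 9 from 22043455 to 22043631 and had 1018.8 normalised tags, rank 3 in the list by that measure, at 51.1-fold over control. The control held 23 tags there, at the 99.9th percentile of the list. Its focus ratio was 0.551 against a list median of 0.825, lower than in all but 0.632% of Zfp809 peaks, which means that tags did not flank the centre as they do at a point-like binding site. The Zfp809 gene is on chromosome 9, and the ChIP was made from cells transfected with a plasmid carrying its coding sequence, so plasmid DNA is an explanation to check, beside high control coverage. Neither was tested for this peak, and no gene annotation of the build was used. The one such peak in the Sumo2 list, on chromosome 11 from 108873119 to 108873255, had a focus ratio of 0.614 and 148.8 control tags.

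The first pattern weighed is the overlap between factors far above shifted lists. Regional density of peaks, by which lists gather in the same megabases without sharing sites, would have let shifts of 20 to 200 kb give as many overlaps as observed. The lowest excess over such shifts among the 6 pairs was 28.1-fold, which argues against it. High control coverage, as at repeats that collect reads in any library, was weighed next. If it made the sites with all 4 factors, most should be lost without the 5% of peaks with the most control tags. Of the 927 sites, 692 or 74.7% were left. Control tags above the limits of that cut thus cannot account for most of them (4.5 for Chaf1a, 3 for Zfp809, 2.9 for Sumo2, 5.8 for Trim28). The cut does not reach a lower excess, or one that a sparse control misses, and 51.9% of Zfp809 peaks had the lowest control value. What remains open is control coverage below those limits, any source of false peaks that the control tags do not show, and open chromatin that any ChIP enriches. None of these was tested, and binding of the 4 factors at the same elements may be only a part of the overlap.

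The second pattern is the rank of the strongest sites with all 4 factors at the top of every list. These sites were chosen by their mean score percentile over the lists, so a high rank follows at least in part from the rule. Their peaks had a median control percentile of 99.9 within their own lists (99.87 before rounding), and 38 of 40 exceeded the 95th percentile. In the Zfp809 list all did so but the peak on chromosome 9, at 51.9. Outside that list, strong peaks without all 4 factors often did so too: of the 50 strongest such peaks, 94% for Chaf1a, 64% for Sumo2 and 60% for Trim28. For Zfp809 the share was 14% (6.95 to 26.2), so high control was uncommon at its strong peaks without all 4 factors. Only 10 of the 40 peaks, from 5 sites, had at least 10 stronger peaks of that kind in their list, and their median control percentile among up to 20 of these was 68.8, too few to decide whether sequence that collects reads in any library lifted these sites, which stays open. The 920 sites with all 4 factors on placed chromosomes had median control tags of 2 for Chaf1a, 1 for Zfp809, 1 for Sumo2 and 3.5 for Trim28, against list medians of 2, 0.5, 1 and 3. The 95th percentile of control tags was exceeded at 10% of them for Chaf1a, 4.35% for Zfp809, 12.3% for Sumo2 and 11.4% for Trim28. In the whole lists, where ties lower the share, 547 of 11354 Chaf1a, 423 of 18197 Zfp809, 2425 of 51628 Sumo2 and 1004 of 24255 Trim28 peaks exceeded it. The share at these sites was thus the larger in every list. Peaks at these sites also scored higher than their lists. Their median score percentile was 66.7 for Chaf1a, 66.5 for Zfp809, 95.7 for Sumo2 and 93.3 for Trim28. The shares were not matched for score, so the difference may reflect strength. No biological explanation was tested.

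The third pattern is a spacing in the Trim28 list, in which pairs of peaks 5 to 7 kb apart were 1.64 times as dense (95% interval 1.38 to 1.92 from 2000 draws of chromosomes) as pairs 3 to 4.5 kb apart, a step also seen for Chaf1a at 1.38 (1.17 to 1.64) but not for Zfp809 at 1.01 (0.891 to 1.13) or Sumo2 at 1.005 (0.955 to 1.05). HOMER's local background filter can remove peaks near stronger ones, and it was first held that pairs with tag counts within 2-fold of each other would then show no step. They did, at 1.385 (1.15 to 1.63), but the criterion was wrong. A calculation added after that value was seen left only 365 of 661 such pairs and predicted 1.81 (1.73 to 1.91). It used a 4-fold limit, the lowest local fold in the Trim28 list, and assumed a 10 kb local region. With this limit and region the filter could make a step larger than the one seen, though the calculation also predicted 1.23 for all Zfp809 pairs, where no step was seen. The filter cannot be told apart from a real spacing, since the size of its local region is not given. A preferred spacing, as between both long terminal repeats of a provirus, needs pairs 5 to 7 kb apart to exceed those 8 to 12 kb apart as well, and that ratio was 1.159 (1.06 to 1.26), but it was also above 1 for Zfp809 at 1.47 (1.32 to 1.64) and Sumo2 at 1.18 (1.13 to 1.23), which lack the step, and 1.09 (0.946 to 1.22) for Chaf1a, and no repeat annotation was at hand to decide.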
